A study of Homo sapiens with 12 samples.

How the data were processed

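RNA from U2OS-ERα cells was measured on 12 Affymetrix Human Gene 1.0 ST arrays, 3 biological replicates in each of 4 groups. Cells were transfected with 50 nM of a non-targeting or an SRC-1 siRNA pool and moved the next day to medium with charcoal-stripped serum, in which they received ethanol vehicle or estradiol for 3 h. The design text also names a GSK3 siRNA pool; no array of such cells is among the 12, and it is not analysed here. Replicate numbers were taken from the sample titles.

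The deposited values are log2 expression per probe set, normalized across arrays by the authors with the affy package. The authors tested with limma; neither version is stated, nor are the background correction, normalization and summarization. The values were used as deposited. Of 33297 probe sets, 4203 with identifiers below the first one listed for a gene (7896740) were taken as control probe sets and left out; this was inferred from the identifiers and is not stated in the sources used here. Among the 29094 tested, 19460 carry 1 gene symbol, 1754 several and 7880 none, and 769 of 18417 symbols have several probe sets. Entrez identifiers matched the human reference annotation for 19429, with 0 symbols changed. No depth applies to arrays; their number limits the precision.

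One model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes variances (3.15 prior and 8 residual degrees of freedom). The contrasts were the estradiol effect with each siRNA, the knockdown effect with each treatment, the difference of the estradiol effects, and both effects averaged. A probe set was called at an unadjusted p under 0.01 and a Benjamini-Hochberg adjusted p under 0.05, the threshold of the design text. Tests are two-sided. Chance overlaps assume independent calls. The relative size of the estradiol response is the mean effect with SRC-1 siRNA divided by that with non-targeting siRNA, over probe sets called in the averaged effect, which is independent of the difference tested by design; fry tested the difference.

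Fixed before the data were examined were the contrasts, the thresholds, 32 gene lists with 761 genes, of which 688 were measured, and the rule for naming genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists with at least 5 measured genes in each contrast, with 1 probe set per gene, the one with the highest mean. The list of mitochondrially encoded genes had fewer and was not tested. Other settings of the list test were an estimated correlation and fry. In the 5 contrasts, in order, 0 of 4, 5, 2, 7 and 1 called lists had a median, mean and test of differing sign, against 11 of 27, 7 of 26, 6 of 29, 4 of 24 and 8 of 30 of the others, whose directions are not given.

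Named genes come from probe sets with 1 symbol. They are NCOA1, ESR1, GSK3A and GSK3B; for each contrast, up to 12 highest and 12 lowest fold changes among called probe sets with groups that do not overlap; and, for each list and contrast, up to 4 called members with the smallest p, or up to 2 members with the highest mean, values only, where none is called.

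Alternatives planned before the data were examined were a replicate block, a fit of the compared arrays only, leaving out the lowest 40% of probe sets by mean, a renewed quantile normalization, median centring, a trended and robust variance, array weights, probe sets with 1 symbol only, each array left out, a fold change of at least 1.5, an adjusted p under 0.01, other ways to choose or test the ratio sets, and other list tests. The array mean of the left-out probe sets as a covariate, and testing all probe sets, were added after seeing the data. This covariate lay between -0.159 and -0.024 log2 in the vehicle arrays and between -0.003 and 0.178 in the estradiol arrays. It thus separates the treatments, so adjusting for it can take up estradiol effects and raises their standard errors. A call lost with it does not by itself show an artifact.

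The tests were tried on simulated data with 200 changed of 29094 probe sets. A change of 0.4, 0.7 or 1 log2 was found in 64.2%, 95.5% and 97% of cases for the estradiol effect, with 2.8% false calls, in 64.2%, 89.6% and 97% for the knockdown effect, with 5.1%, and in 40.3%, 73.1% and 89.4% for the difference, with 8.8%. With a true ratio of 1, 20 simulated ratios lay between 0.991 and 1.01, with a mean of 0.956 when the set was chosen on the non-targeting effect, and 1 of the 20 had a fry p under 0.05. These ratios were simulated for increases only, with no repressed set. Errors were drawn independently for each probe set and array, whereas the estimated correlation in the real induced set was 0.079. The simulated range therefore does not measure the spread of a ratio in real arrays. Of 201 simulated lists, the 1 that was shifted was called and 0 of 200 others by camera. These lists were random probe sets with independent errors. Estimated correlations in real lists were higher than the preset in places, at 0.15 for cytokines and 0.309 for cholesterol genes. The simulation thus does not show how often camera calls correlated lists falsely. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.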

Results

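Gene expression was measured in U2OS-ERα cells, human osteosarcoma cells that carry estrogen receptor α, on 12 arrays with 33297 probe sets each. The cells had received 50 nM of a non-targeting siRNA pool or of a pool against SRC-1, the nuclear receptor coactivator encoded by NCOA1, and then ethanol vehicle or estradiol for 3 h. The 4 groups held 3 biological replicates each, as labelled, and p-values measure the spread among these. Array medians lay between 6.858 and 6.901 on the log2 scale, and arrays of 1 group correlated across probe sets at 0.9967 to 0.9979. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.071 log2. Signal over background was not measured. The lower quartile of the arrays was 5.13 to 5.19 log2, and of the named genes KLRC4-KLRK1, KLRC3, KLRC2, SYTL5, MOS, HEMGN, PARGP1 and LYZ had a mean below it in at least 1 group, where their signal is not shown to exceed background. No genome build is named with the values, so genes are given by symbol and probe set without positions.

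NCOA1 transcripts (probe set 8040552) fell 7.60-fold with SRC-1 siRNA in vehicle-treated cells and 4.64-fold in estradiol-treated cells. The difference between vehicle arrays was -2.93 ± 0.11 log2 (SE). The mean was 8.79 ± 0.06 log2 (SD, n = 3) with non-targeting siRNA and 5.86 ± 0.29 with SRC-1 siRNA under vehicle, and 9.08 ± 0.07 and 6.86 ± 0.07 under estradiol. The transcript left was 13.2% and 21.5% of the level with non-targeting siRNA (adjusted p = 7.3e-07 and 7.92e-06). If background adds to the signal, these folds are lower limits and these shares upper limits. With SRC-1 siRNA, estradiol raised NCOA1 2.00-fold (adjusted p = 0.00029); with non-targeting siRNA the log2 difference was 0.29 (adjusted p = 0.275), which was called without vehicle replicate 1 of the SRC-1 siRNA arrays, at the same 0.29. The difference between these effects was 0.71 log2 with a 95% interval from 0.36 to 1.06, and its adjusted p was 0.442 over all probe sets and 0.00463 over the 5 probe sets fixed for NCOA1, ESR1, GSK3A and GSK3B. With the array mean of the left-out probe sets as a covariate, the NCOA1 rise with SRC-1 siRNA went from 1.00 ± 0.11 to 0.53 ± 0.21 log2 (SE) and was no longer called. The effect with non-targeting siRNA went from 0.29 to 0.065 ± 0.129, and the difference from 0.71 to 0.47 ± 0.16 (limma adjusted p = 0.743).

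ESR1, which encodes estrogen receptor α, had means of 12.16, 12.15, 12.11 and 12.03 log2 in probe set 8122843 with non-targeting siRNA and vehicle, non-targeting siRNA and estradiol, SRC-1 siRNA and vehicle, and SRC-1 siRNA and estradiol. Its other probe set, 8122840, read much lower, at 5.54 log2 with non-targeting siRNA and vehicle, a little above the lower quartile of the arrays. GSK3A and GSK3B, which encode the glycogen synthase kinase 3 isoforms, had means of 10.26 and 10.87 log2 in that group. None of these 4 probe sets was called by limma in any comparison, except that ESR1 8122843 was called for knockdown under estradiol with a trended and robust variance, at -0.12 log2.

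Estradiol with non-targeting siRNA asks which genes the hormone changes within 3 h when SRC-1 is present. C3, the central complement component, rose 8.22-fold (log2 3.04 ± 0.10 SE, 3 arrays per group), and MANEAL, a homologue of an endomannosidase, rose 6.56-fold (log2 2.71 ± 0.08). HOXD10, a homeobox transcription factor, rose 5.68-fold, KRT19, a keratin of simple epithelia, 4.38-fold, and LOXL4, a lysyl oxidase that crosslinks collagen, 4.18-fold. The largest decreases were smaller: LRRC4C, a synaptic adhesion protein, fell 1.82-fold, AMIGO2, another adhesion protein, 1.73-fold, and TGFB2, a TGF-beta ligand, 1.68-fold. The MAP kinase phosphatase genes DUSP10 and DUSP5 fell 1.65-fold and 1.58-fold, and the interleukin gene IL6 1.57-fold.

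In limma, 793 of 29094 probe sets were called, 539 higher and 254 lower with estradiol, and 53 changed at least 2-fold, each of them upward. Among the 12 highest were also SYTL5, CMKLR1, YPEL2 and ADAMTSL5, at 1.86 to 2.17 log2. KLRC4-KLRK1 (3.15 log2), KLRC3 (2.94) and KLRC2 (2.38) are natural killer receptor genes of near-identical sequence, whose probe sets may not be told apart by hybridization. Their vehicle means of 4.39, 4.65 and 3.84 log2 lay below the lower quartile of the arrays, so these changes are not exact. The lowest also held GPR137C, LURAP1L, CITED2, TRIB1 and ARHGAP29, at -0.59 to -0.72 log2. In all 793 called probe sets every array of one group lay beyond every array of the other, as did 21% of all tested probe sets, where chance gives 10%. With the mean of the left-out probe sets as a covariate the count was 366, of which 322 were among the 793. The median size of the 793 effects went from 0.379 to 0.367 log2, all with the same sign, and their median standard error from 0.06 to 0.08.

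**Figure D1:**
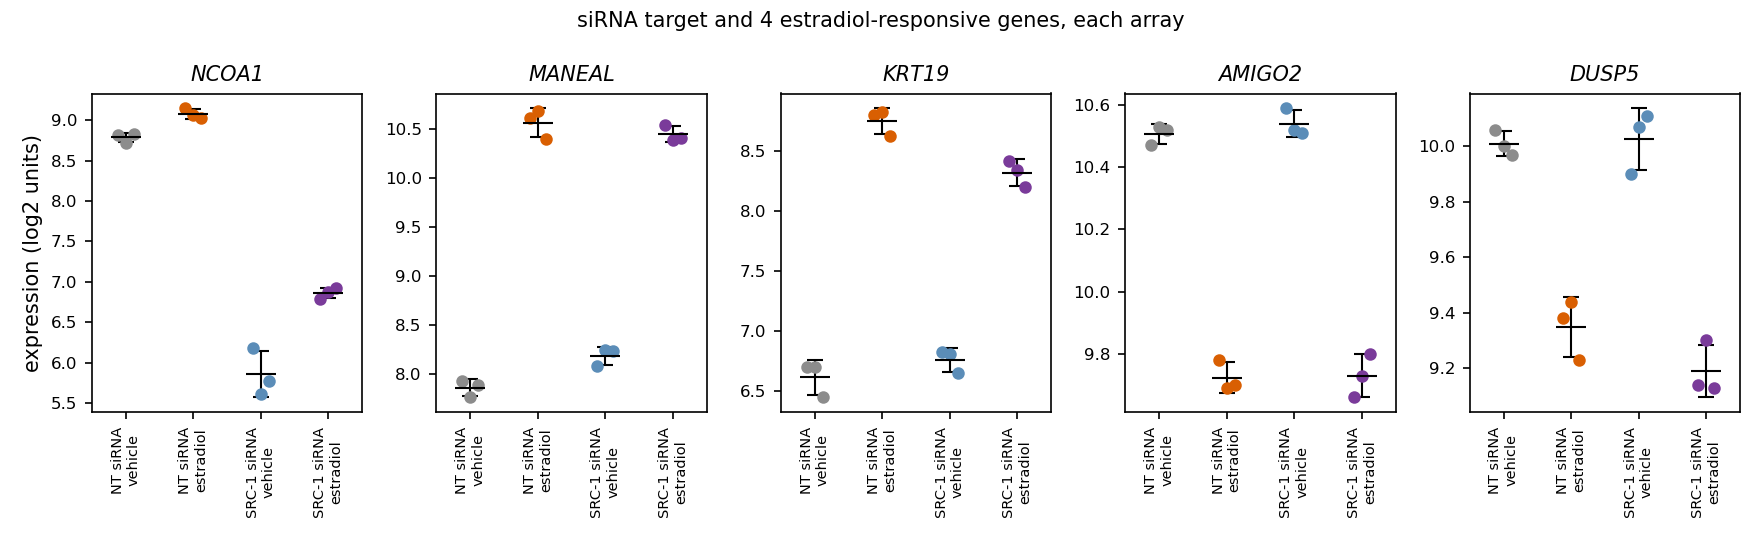
Log2 expression (y axis, not starting at 0) of NCOA1, MANEAL, KRT19, AMIGO2 and DUSP5 in each array of the 4 groups (x axis, 3 arrays per group); points are arrays, horizontal bars means and error bars SD. MANEAL and KRT19 lie higher and AMIGO2 and DUSP5 lower in every estradiol array than in every vehicle array with the same siRNA.

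Genes that estrogen induces in breast cancer cells rose as a group in these bone cells. Of 34 measured members, 11 were called higher and 1 lower (13 and 1 adjusted over the list alone), with a mean change of 0.26 log2 and an adjusted camera p of 1.64e-10. CA12, a carbonic anhydrase, rose 2.53-fold, HSPB8, a small heat-shock protein, 1.80-fold, and ABCA3, a lipid transporter, 1.79-fold, besides KRT19; MYC, a member in breast cancer cells, fell 1.30-fold. Of the 12 genes known to be repressed by estrogen there, 3 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.0375 for a downward shift, and 0.552 with an estimated correlation), among them ZFP36L1, an RNA-binding protein that destabilizes transcripts, at -0.48 log2. The estrogen-induced list held its call with an estimated correlation (adjusted p = 0.00866), here and with SRC-1 siRNA, as did no other list called in any comparison. The call of the repressed list was also lost with the covariate (0.083). Leaving out vehicle replicate 1 (0.0505) or 2 (0.0756) or estradiol replicate 1 (0.0683) or 3 (0.0609) with non-targeting siRNA ended it too, as did vehicle replicate 1 (0.0698) or estradiol replicate 1 (0.051) with SRC-1 siRNA.

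Immediate-early genes, which serum and growth factors switch on within minutes, went in both directions, with 5 of 34 called higher and 10 lower (the same numbers adjusted over the list alone; adjusted p = 0.106 by camera). Without estradiol replicate 2 with non-targeting siRNA, camera called the list downward (0.00869). ZFP36, which speeds the decay of cytokine transcripts, rose 2.01-fold, IER3 1.99-fold and FOSL2, an AP-1 subunit, 1.71-fold, whereas TRIB1, a pseudokinase, fell 1.57-fold. Among NF-kB targets, cytokines and chemokines, 5 of 27 rose and IL6 fell (7 and 3 adjusted over the list alone; adjusted p = 0.106): the cytokine gene LIF rose 2.17-fold, the prostaglandin synthase gene PTGS2 2.10-fold and CSF1, the macrophage growth factor, 1.80-fold. Extracellular matrix and mesenchymal genes had 5 of 33 called higher and 0 lower (5 and 2 adjusted over the list alone; adjusted p = 0.207 by camera and 0.0168 by fry). Those were led by LOX, which crosslinks collagen, at 2.28-fold, TIMP3, an inhibitor of metalloproteinases, at 2.07-fold, and the transcription factor SNAI1 at 1.80-fold.

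Cholesterol synthesis genes and other SREBP2 targets shifted downward with estradiol and non-targeting siRNA (mean -0.10 log2, 18 measured, adjusted p = 0.00176, and 0.552 with an estimated correlation). Called members were HMGCS1, an early enzyme of the pathway, at -0.27 log2, and INSIG1, which retains SREBP in the endoplasmic reticulum, at -0.30 (4 lower adjusted over the list alone), and they kept their calls in 9 and 6 of the 12 fits that left out 1 array and lost them with the covariate. G1/S and DNA replication genes shifted upward by a mean of 0.06 log2 (35 measured, adjusted p = 0.00176, and 0.552 with an estimated correlation), although the only 2 called were E2F7, a repressor of E2F targets, which fell 1.33-fold, and CDKN1A, a cyclin-dependent kinase inhibitor, which rose 1.29-fold and lost its call with the covariate (6 higher and 1 lower adjusted over the list alone). Leaving out estradiol replicate 3 with non-targeting siRNA ended the cholesterol call (0.0609), and leaving out replicate 1 ended the G1/S call (0.0685). Of 10 splits of the compared arrays, 2, the real one included, called at least the 4 lists called here. Chance is therefore not excluded for the number of lists called.

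Estradiol with SRC-1 siRNA asks for the same response in cells depleted of SRC-1 transcripts. C3 rose 6.62-fold (log2 2.73 ± 0.10 SE, 3 arrays per group), HOXD10 5.87-fold, LOXL4 5.03-fold, MANEAL 4.80-fold and ADAMTSL5, a secreted matrix protein, 3.87-fold. OTUB2, a deubiquitinase, rose 3.80-fold (log2 1.93 ± 0.05). MMP1, the interstitial collagenase, fell 1.83-fold, DUSP5 1.79-fold, TRIB1 1.76-fold, AMIGO2 1.76-fold and CITED2, a regulator of p300-dependent transcription, 1.68-fold. MYCT1, ESM1, an endothelial proteoglycan, MOS, a kinase of the MAP kinase pathway, and KLF5, a Krüppel-like factor, fell by 1.64-fold, 1.63-fold, 1.62-fold and 1.59-fold.

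In all, 2001 probe sets were called, 1307 higher and 694 lower, and 65 changed at least 2-fold, all upward. A renewed quantile normalization moved the share called higher from 65.3% to 48.3% (1108 of 2293), so the balance of directions depends on scaling, while the median of all genes stayed at -0.02 log2 in the deposited values. Of the called, 1996 had groups that did not overlap, as did 25.8% of all tested, where chance gives 10%. The 4203 left-out probe sets, taken as controls, moved in the same comparison: their mean deviation rose from -0.091 ± 0.067 log2 (SD, n = 3) to 0.135 ± 0.042, and 323 of them would be called, 320 higher. Their median change was 0.355 log2 for the 1990 with a mean of 4 to 8 log2 and 0.005 for the 1029 above 10, while tested probe sets moved by -0.048 and -0.003 at these levels. With non-targeting siRNA they went from -0.076 ± 0.043 to 0.032 ± 0.036, with 0 called by limma and 510 at an unadjusted p under 0.05. With their array mean as a covariate 106 probe sets were called, 96 of them among the 2001, as the median standard error of these 2001 effects rose from 0.065 to 0.135 log2 and their median size went from 0.344 to 0.243. The count was 1042 without vehicle replicate 2, 1242 without vehicle replicate 3, 1205 without estradiol replicate 1 and 1289 without estradiol replicate 3 of the SRC-1 siRNA arrays, and 958 with only the compared arrays in the fit.

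**Figure D2:**
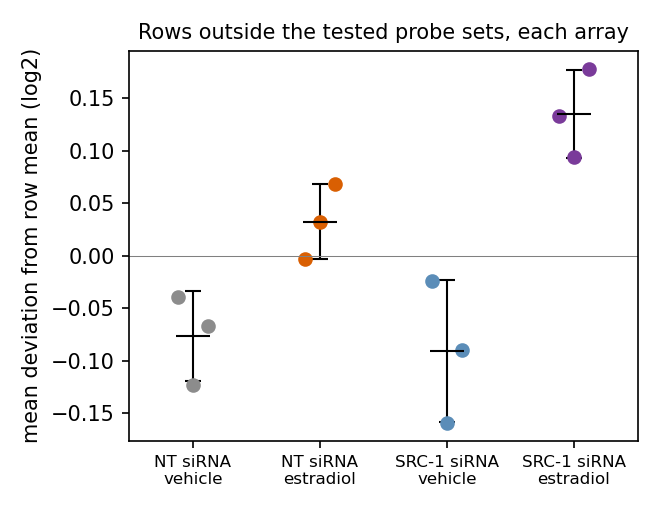
Mean deviation of the 4203 left-out probe sets from their mean over all arrays (y axis, log2) in each array of the 4 groups (x axis, 3 arrays per group); points are arrays, horizontal bars means and error bars SD. The 3 estradiol arrays with SRC-1 siRNA lie between 0.094 and 0.178, above the other 9.

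The estrogen-induced list rose here as well, with 13 of 34 members called higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 1.92e-07, and 0.0265 with an estimated correlation). CA12 rose 3.05-fold, KRT19 2.94-fold, HSPB8 1.99-fold and SLC22A5, a carnitine transporter, 1.47-fold. Of 34 immediate-early genes, 6 rose and 12 fell (6 and 14 adjusted over the list alone), a downward shift at an adjusted p of 0.0252 (0.7 with an estimated correlation), with IER3 2.12-fold and FOSL2 1.89-fold higher. Wnt target genes shifted downward by a mean of -0.13 log2 (3 of 18 called lower, 5 adjusted over the list alone, adjusted p = 0.031, and 0.456 with an estimated correlation), with the transcription factor gene MYC at -0.47 log2 and BMP4, a bone morphogenetic protein, at -0.31. G1/S genes (1 of 35 higher and 1 lower, the same adjusted over the list alone, adjusted p = 0.0138, and 0.683 with an estimated correlation) and G2/M genes (1 of 29 higher, 0 adjusted over the list alone, adjusted p = 0.0441, and 0.7 with an estimated correlation) shifted upward, by means of 0.05 log2 each. With the covariate the adjusted p was 0.612 for immediate-early genes, 0.987 for G2/M genes, 0.745 for Wnt targets and 0.456 for G1/S genes.

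Leaving out single arrays ended these 4 list calls, while the estrogen-induced call held in all 12 fits. Vehicle replicate 3 or estradiol replicate 3 of the SRC-1 siRNA arrays ended the immediate-early call (0.0608 and 0.0571), and vehicle replicate 1 or estradiol replicate 3 the Wnt target call (0.0888 and 0.0571). For G1/S genes it was vehicle replicate 3 and estradiol replicate 1 (0.0608 and 0.0865). For G2/M genes it was vehicle replicates 2 and 3 and estradiol replicates 1 and 3 (0.0637, 0.255, 0.129 and 0.0872), and vehicle replicate 1 with non-targeting siRNA (0.05). Of the genes named here for this comparison, MMP1, DUSP5, TRIB1, MYCT1, ESM1, MOS, KLF5, MYC, BMP4 and SLC22A5 were no longer called with the covariate. As the covariate separates estradiol from vehicle arrays, lost precision could give the same outcome.

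Of the 793 probe sets called for estradiol with non-targeting siRNA, 625 were also called with SRC-1 siRNA, where 2001 were called. Of those called higher, 467 were shared where chance gives 24.2, and of those called lower 158 where chance gives 6.06; 0 were called in opposite directions. Of the 793, 777 (98%) had the same sign with SRC-1 siRNA. Across all tested probe sets, which are not independent replicates, Pearson's r between the effects was 0.628 and Spearman's rho 0.441.

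**Figure D3:**
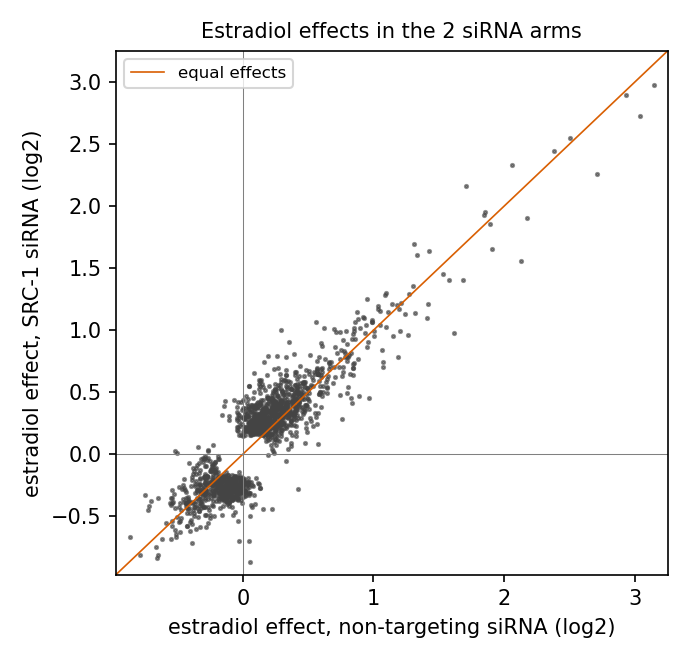
Estradiol effect with SRC-1 siRNA (y axis, log2 fold change) against that with non-targeting siRNA (x axis, log2 fold change); each point is 1 of 1487 single-symbol probe sets called in either comparison. Of these, 84 have effects of opposite sign.

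Whether SRC-1 siRNA alters the response of single genes was tested as the difference of the estradiol effects. KRT19 rose 4.38-fold with non-targeting and 2.94-fold with SRC-1 siRNA, a log2 difference of -0.57 with a 95% interval from -0.84 to -0.31. MANEAL differed by -0.45 (-0.70 to -0.20), MMP1 by -0.93 (-1.27 to -0.58) and ESM1 by -0.75 (-1.1 to -0.41). Values less negative with SRC-1 siRNA gave positive differences for TGFB2 (0.42, 0.13 to 0.70), LURAP1L (0.33, 0.11 to 0.54) and IL6 (0.29, 0.04 to 0.55). YPEL2 (-0.04, -0.24 to 0.17) and AMIGO2 (-0.02, -0.17 to 0.13) had narrow intervals around 0. KRT19, TGFB2, LURAP1L and IL6 were among the extreme effects with non-targeting siRNA, and MMP1 and ESM1 among those with SRC-1 siRNA. Such a choice favours differences of the signs seen for these genes, and the intervals are not adjusted for it. MANEAL was among the extremes with either siRNA.

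No probe set passed the test: limma called 0 of 29094, the smallest adjusted p being 0.392, with 2102 at an unadjusted p under 0.05. With a trended and robust variance limma called 2, both lower: FST, an antagonist of activins, with a difference of -0.64 ± 0.08 log2 (SE, adjusted p = 0.0106), and LOX, with -0.40 ± 0.06 (adjusted p = 0.0379). These 2 were singled out after their values were seen. Intervals of 16 of the 24 genes named for non-targeting siRNA cover 0, and the median half-width of an interval was 0.221 log2. In simulated data the test found 40.3% of differences of 0.4 log2 and 89.4% of differences of 1 log2. Among the 31 lists, camera called a difference for the cholesterol list, with a mean of 0.09 log2 (0 of 18 members called, 3 at an unadjusted p under 0.05, 0 with a trended and robust variance, 0 adjusted over the list alone; adjusted p = 0.00463). Its adjusted p was 0.983 with an estimated correlation, 0.778 by fry and 0.3 with the covariate, and it was 0.126 without estradiol replicate 3 of the non-targeting siRNA and 0.0528 without vehicle replicate 2 of the SRC-1 siRNA arrays. Matrix genes (adjusted p = 0.101) and ATF4 genes (0.141) were called lower with a trended and robust variance (0.0387 and 0.039). Matrix genes were also called without vehicle replicate 2 (0.0254) or estradiol replicate 2 (0.00789) of the non-targeting or vehicle replicate 3 (0.0402) or estradiol replicate 1 (0.0418) of the SRC-1 siRNA arrays. That last fit also called ATF4 genes (0.0418), and the first Wnt targets (0.035). These 3 lists had an adjusted p of 0.983 with an estimated correlation and of 0.778 by fry.

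Over probe sets called in the averaged estradiol effect the response was larger with SRC-1 siRNA, which another choice of probe sets did not show. The 1778 probe sets called higher in the averaged estradiol effect rose by a mean of 0.30 log2 with non-targeting and 0.39 with SRC-1 siRNA, a ratio of 1.30, and 72.2% were larger with SRC-1 siRNA (fry adjusted p = 0.0287 over 2 sets). The 1120 called lower fell by 0.21 and 0.26 log2, a ratio of 1.24, with 65.2% larger (fry adjusted p = 0.0287). Over the 539 induced and 254 repressed probe sets called with non-targeting siRNA the ratios were 0.995 and 0.777, the latter called by fry as a smaller response. Such a choice lowers the ratio by its construction. It gave a mean of 0.956 for a true ratio of 1 in simulated data, which held increases only and give no measure for the repressed set. Among the 55 induced probe sets with an averaged change of at least 2-fold the ratio was 0.991 (fry adjusted p = 0.528 over 17 parts), and among the 1591 under 1.5-fold it was 1.41 (0.0913). It was 1.72 among 352 induced probe sets without a gene symbol and 1.18 among 1232 with a single symbol (0.0913 and 0.093).

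With the left-out mean as a covariate the ratios over the same probe sets were 1.11 and 1.12, and fry called neither. The induced ratio was not called without vehicle replicate 1 (1.22) or 3 (1.25) or estradiol replicate 1 (1.21) of the non-targeting arrays, and the repressed ratio without any of the 6 non-targeting arrays (1.15, 1.09 and 1.13 for vehicle and 1.09, 1.099 and 1.14 for estradiol replicates 1 to 3) or without vehicle replicate 2 of the SRC-1 siRNA arrays (1.13).

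SRC-1 siRNA under vehicle asks what the SRC-1 siRNA pool changes without hormone. As a single pool was used, SRC-1 depletion and effects of the pool on other transcripts cannot be told apart, under either treatment. Besides NCOA1, IL1A, an interleukin, fell 1.93-fold (log2 -0.95 ± 0.07 SE, 3 arrays per group), the neutrophil chemokine gene CXCL8 1.92-fold and the chemokine gene CCL20 1.89-fold. GPR180 fell 2.06-fold, GPR65, a proton-sensing receptor, 1.97-fold, MTMR4, a phosphoinositide phosphatase, 1.94-fold and SS18, a subunit of BAF chromatin remodelling complexes, 1.76-fold. CRCT1, a gene of epidermal differentiation, fell 2.08-fold. Increases were smaller: PTPN22, a tyrosine phosphatase, rose 1.62-fold, FST 1.51-fold, LOX 1.39-fold and CAV1, the main protein of caveolae, 1.35-fold.

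In this comparison 352 probe sets were called, 77 higher and 275 lower, and 4 changed at least 2-fold. KLHL5, NCEH1 and TOR1AIP2 were also among the 12 lowest, at -0.95, -0.88 and -0.87 log2, and PSTPIP2 and CBX6 among the 12 highest, at 0.44 and 0.38. In all 352 the groups did not overlap, as in 18.4% of all tested, where chance gives 10%. Of the other highest, ATP8B1, ARHGAP29, HEMGN, ERBB3, LOC643406 and SNORD14E kept their calls in 10, 11, 7, 10, 9 and 3 of the 12 fits that left out 1 array. The count was 169, 229 and 185 without vehicle replicates 1 to 3 of the non-targeting arrays and 201 and 230 without vehicle replicates 2 and 3 of the SRC-1 siRNA arrays. It was 90 with only the compared arrays in the fit, 728 without dim probe sets and 857 with a trended and robust variance.

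NF-kB targets, cytokines and chemokines shifted downward under vehicle, with 9 of 27 called lower and none higher (11 adjusted over the list alone, mean -0.22 and median -0.08 log2, adjusted camera p = 2.69e-07, and 0.596 with an estimated correlation). The 17 members called under neither treatment, a set chosen for weak changes, had a mean of -0.055 log2 over both treatments. ICAM1, a leukocyte adhesion receptor, fell 1.42-fold and IL24, a cytokine of the IL-10 family, 1.49-fold. By fry, which tests whether its genes move one way, the adjusted p of the list was 0.0098. Glycolysis and hypoxia genes shifted downward (4 of 25 lower, 5 lower and 1 higher adjusted over the list alone, adjusted p = 0.00315, and 0.665 with an estimated correlation), with the glucose transporter gene SLC2A3 at -0.44 log2 and NDRG1, a hypoxia-induced gene, at -0.25. Of 10 splits of the compared arrays, 3, the real one included, called at least the 2 lists called here. Chance is therefore not excluded for the number of lists called.

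SRC-1 siRNA under estradiol asks the same in hormone-treated cells. BCL2A1, an antiapoptotic BCL2 relative and NF-kB target, fell 2.57-fold (log2 -1.36 ± 0.10 SE, 3 arrays per group), CXCL8 2.57-fold, CCL20 2.33-fold, MMP1 2.23-fold and IL1A 1.99-fold. CCL3, a macrophage chemokine, fell 1.99-fold, CRCT1 2.51-fold and GPR65 2.07-fold, and the pseudogene ZNF542P 2.01-fold, a value that related sequences may share. ATP8B1, a phospholipid flippase, rose 1.53-fold and PALLD, an actin-associated protein, 1.41-fold.

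Here 524 probe sets were called, 213 higher and 311 lower, and 8 changed at least 2-fold, all downward. GRAMD1B and MYCT1 were also among the 12 lowest, at -0.97 and -0.92 log2. In all 524 the groups did not overlap, as in 22.3% of all tested, where chance gives 10%. Of the 12 highest, ATP8B1 and PALLD kept their calls in all 12 fits that left out 1 array, while RIPOR2, PDLIM1, TGFB2 and the 2 probe sets of the pseudogene PARGP1, which hold identical values, kept them in 8, MMP12 and ARRDC3 in 7, GASK1B in 6, and PLAC8 and KIAA1107 in 4. With the covariate, ATP8B1 kept its call and the other 11, PALLD among them, lost theirs. The count was 285, 216 and 290 without estradiol replicates 1 to 3 of the non-targeting arrays and 245 and 249 without estradiol replicates 1 and 3 of the SRC-1 siRNA arrays. It was 174 with only the compared arrays in the fit, 1117 without dim probe sets, 1246 with a trended and robust variance and 121 with the covariate, 14 higher and 107 lower. With it the median size of the 524 effects went from 0.344 to 0.321 log2, all with the same sign, and their median standard error from 0.056 to 0.073.

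**Figure D4:**
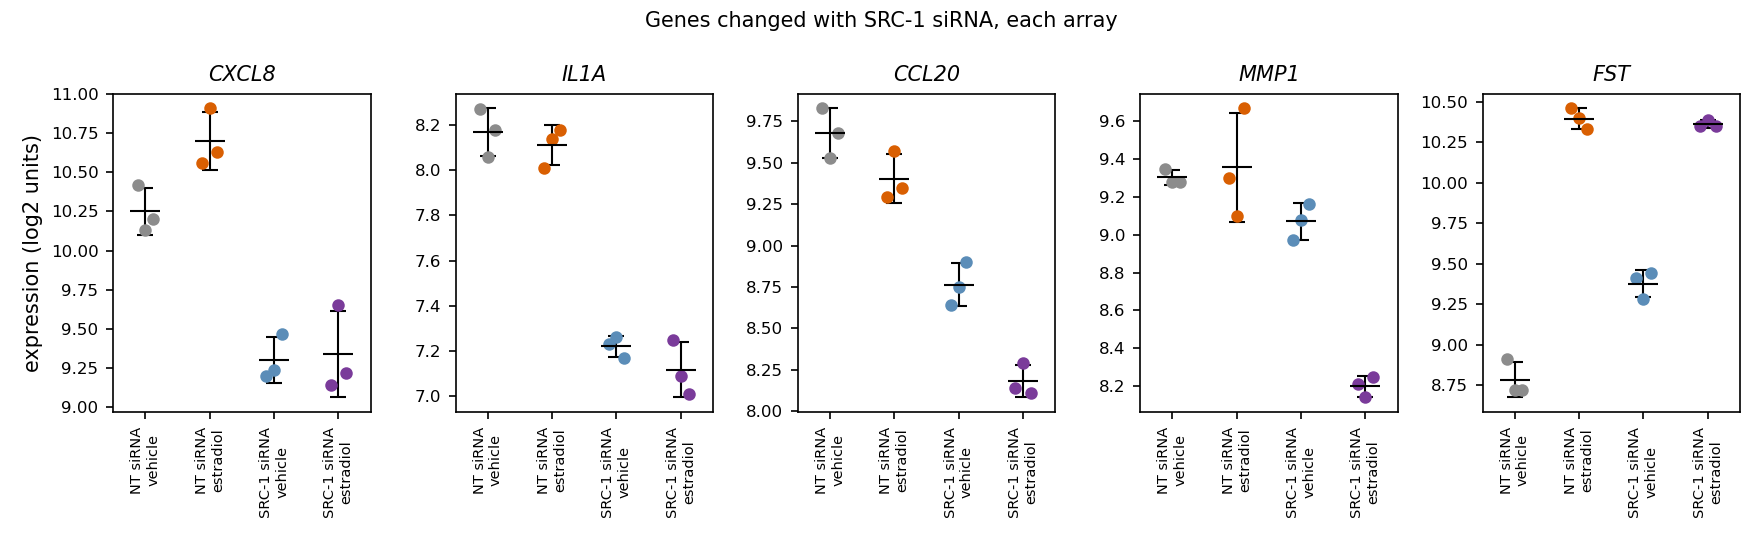
Log2 expression (y axis, not starting at 0) of CXCL8, IL1A, CCL20, MMP1 and FST in each array of the 4 groups (x axis, 3 arrays per group); points are arrays, horizontal bars means and error bars SD. CXCL8, IL1A and CCL20 lie lower in every SRC-1 siRNA array than in every non-targeting array with the same treatment.

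The NF-kB, cytokine and chemokine list shifted downward under estradiol too, with 8 of 27 called lower and none higher (12 adjusted over the list alone, mean -0.28 and median -0.215 log2, adjusted camera p = 5.17e-09, and 0.365 with an estimated correlation). The next 4 lists each had an adjusted p of 0.531 with an estimated correlation. Cholesterol genes shifted upward by a mean of 0.12 log2 (2 of 18 higher, 5 adjusted over the list alone, adjusted p = 3.84e-06), in a comparison that shares its non-targeting estradiol arrays with the downward shift given above. The called members were LSS, lanosterol synthase, and MSMO1, a later enzyme, at 0.27 and 0.30 log2, which kept their calls in 3 and 2 of the 12 fits that left out 1 array and lost them with the covariate. ATF4 and amino-acid response genes shifted downward (3 of 23 lower, 7 adjusted over the list alone, adjusted p = 0.000945), among them CHAC1, a glutathione-degrading enzyme, at -0.32 log2, not called with the covariate. Glycolysis and hypoxia genes (3 of 25 lower, 3 adjusted over the list alone, adjusted p = 0.0111, with SLC2A3 at -0.58 log2) and extracellular matrix genes (3 of 33 lower and 1 higher, 8 and 1 adjusted over the list alone, adjusted p = 0.0183, with MMP1 lowest) shifted downward. The glycolysis call was lost with the covariate (0.0539), and the matrix call without estradiol replicate 3 of the SRC-1 siRNA arrays (0.0707). Of 10 splits of the compared arrays, 2, the real one included, called at least the 7 lists called in this comparison. Chance is therefore not excluded for the number of lists called.

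Immediate-early genes also shifted downward (1 of 34 lower and 1 higher, the same adjusted over the list alone, adjusted p = 0.0396, and 0.656 with an estimated correlation), although the called members were NR4A3, a nuclear receptor, at -0.28 log2 and JUN, an AP-1 subunit, at 0.23, which kept their calls in 7 and 1 of the 12 fits that left out 1 array and lost them with the covariate. The list call was lost without estradiol replicate 2 of the non-targeting (0.523) or replicate 3 of the SRC-1 siRNA arrays (0.229) and with the covariate (0.41). Leukocyte markers shifted downward at an adjusted p of 0.0431 (0.595 with an estimated correlation), with LYZ, lysozyme, the only member called of 16 (-0.35 log2, not called with the covariate; 3 adjusted over the list alone). That call was lost in 6 of the 12 fits that left out 1 array: vehicle replicates 2 and 3 and estradiol replicates 1 and 2 with non-targeting siRNA (0.0501, 0.0528, 0.0583 and 0.0535), and estradiol replicates 1 and 2 with SRC-1 siRNA (0.138 and 0.0547). It was also lost with the covariate (0.797). G2/M genes were called higher without estradiol replicate 1 of the non-targeting arrays (0.0288).

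The knockdown effects under vehicle and estradiol shared 38 probe sets called higher, where chance gives 0.564, and 174 called lower, where chance gives 2.94, with 0 in opposite directions. Across all tested probe sets Pearson's r between these effects was 0.32 and Spearman's rho 0.248. Averaged over treatments, SRC-1 siRNA changed 1483 probe sets, 596 higher and 887 lower, and averaged over siRNAs estradiol changed 2898, 1778 higher and 1120 lower (1522 and 1862 after a renewed quantile normalization). Of the induced, 104 were lower with SRC-1 siRNA, where chance gives 54.2, and 92 higher, where chance gives 36.4. Of the repressed, 122 were lower, where chance gives 34.1, and 67 higher, where chance gives 22.9. Every pair of directions thus exceeded chance. Both contrasts share the variance estimate of each probe set, so their calls are not independent, and these counts alone show no link between the effects. The averaged knockdown count was 927 and 909 without vehicle replicates 1 and 3 and 975 and 914 without estradiol replicates 1 and 2 of the non-targeting arrays, and 897 and 920 without estradiol replicates 1 and 3 of the SRC-1 siRNA arrays. With the covariate the averaged estradiol count was 212, as the median size of the 2898 effects went from 0.233 to 0.174 log2 and their median standard error from 0.044 to 0.098. The averaged knockdown count was 863, with the 1483 effects at 0.204 and 0.201 log2 and standard errors of 0.038 and 0.042.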

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

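Of the tests in this part, the covariate, the ratio over bright probe sets, the medians by level and the linear rise of NCOA1 were chosen after the result was seen, and the planned fits without 1 array and list tests were turned to the cytokine list after it was seen.

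Over probe sets called in the averaged effect, the estradiol response was larger with SRC-1 siRNA, by a ratio of 1.30 for induced and 1.24 for repressed ones, but over those called with non-targeting siRNA the ratios were 0.995 and 0.777. A difference between arrays that also moved the left-out probe sets may account for part of the induced excess: with their array mean as a covariate the ratio was 1.11 with 36.5% of the excess left, and for repressed ones, where it stays open, 1.12 with 52.8% left, neither called by fry. In the normalized values it was no shift of whole arrays. Estradiol with SRC-1 siRNA moved left-out probe sets by a median of 0.355 log2 at 4 to 8 log2 and 0.005 above 10, and tested ones by -0.048 and -0.003. Normalization across arrays would remove such a shift, so these medians do not show whether there was one before it. A shift of dim induced probe sets stays open, at a ratio of 1.15 over bright ones, not called by fry. Of 100 splits of the arrays, 4 gave an induced difference as large as the real 0.0904 (highest other 0.116). Another split thus exceeded the real value, so chance is made less likely there but is not excluded. For the repressed difference, 10 splits were as large as the real 0.0494 (highest other 0.0762), so chance is not excluded there either. An effect of SRC-1 depletion on the response stays open and was not tested apart from this difference between arrays.

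NCOA1 was reduced less in estradiol arrays, with a difference of 0.71 ± 0.16 log2 (SE) between the estradiol effects, and of 0.47 ± 0.16 with the covariate. A shift common to tested probe sets of its level is argued against. The NCOA1 effect with SRC-1 siRNA lay at the 99.67 percentile of 4230 of them, whose median was -0.068 log2. NCOA1 was not ranked among the left-out probe sets, which moved by a median of 0.355 log2 at 4 to 8 log2. A shift that reaches only some dim probe sets therefore stays open. An equal amount of signal added with either siRNA is argued against as the only source of the rise. The linear rise with SRC-1 siRNA was 0.581 of that with non-targeting siRNA (95% interval 0.28 to 0.88). This interval uses 8 degrees of freedom although the variances differ between groups, so it may be too narrow. Equal added signal together with a true NCOA1 increase stays open, as the quotient takes the whole non-targeting rise as added signal. With the covariate the estradiol effect with SRC-1 siRNA went from 1.00 ± 0.11 to 0.53 ± 0.21 log2 (SE), a smaller and less precise value that was not called, so the difference between arrays that moved the left-out probe sets may contribute. A higher NCOA1 transcription with estradiol or a less complete knockdown in those cultures stays open, untested.

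The NF-kB, cytokine and chemokine list shifted downward with SRC-1 siRNA in camera, with 9 of 27 members called lower under vehicle and 8 under estradiol. The difference between arrays that moved the left-out probe sets is argued against as the whole cause under estradiol. The list mean there was -0.278 without and -0.272 with the covariate, which moved 42.8% of all tested probe sets in that comparison by more than their standard error. Under vehicle the covariate decides nothing, as it differed between siRNAs by -0.015, within its SD of 0.056. The left-out probe sets themselves hardly moved there, with 0 of 4203 called by limma. Their median change was -0.006 log2, and -0.029 for those at 4 to 8 log2. Against a list mean of -0.224, these values argue against that difference as the whole cause under vehicle too. A single array is argued against, since the largest adjusted camera p under vehicle was 1.13e-05 over the 12 fits that left out 1 array. A correlated block of genes stays open: the list was not called with an estimated correlation (adjusted p = 0.596 and 0.365), but was by fry, which allows for correlation (0.0098 and 0.0027), over a range of 3.68e-08 to 0.596 and 5.25e-10 to 0.365 in all alternatives. SRC-1 depletion and an effect of the siRNA pool on other transcripts both stay open, since pool sequences are not given in the sources used here.

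The cholesterol list differed between the estradiol effects by a mean of 0.093 log2 in camera. Among the left-out probe sets, 323 would be called for estradiol with SRC-1 siRNA.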

How the results depend on the processing

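The covariate and the tests of all probe sets were chosen after the data were seen; the other alternatives were planned. Of 332 values under alternatives, 243 kept their direction, call and size within the limits set, 70 moved, 17 lost their call and 2 reversed; of 6790 values of named genes, 6029 kept their call, 758 lost it, 2 gained it (NCOA1 and ESR1) and 1 reversed, BCL2L11 with SRC-1 siRNA, at -0.01 log2 with the covariate. The replicate block gave 807, 2308, 327, 520 and 0 calls for the 5 contrasts, 3290 and 1464 for the averaged effects and ratios of 1.314 and 1.28; after group means were removed, arrays of 1 number correlated at -0.035 to 0.209 (median 0.0625, over 0.1 in 6 of 18 pairs) and others at a median of -0.021 (2 of 36), and 10 of 12 arrays correlated best with their own number, a hint of pairing from the data, not the design. Signal over background was not measured here.

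For estradiol with non-targeting siRNA the count was 366 with the covariate, 165 at a fold of 1.5, 422 at an adjusted p under 0.01 and 531 to 783 without 1 array; with SRC-1 siRNA it was 106, 302, 801 and 1042 to 2956, and 958 with the compared arrays only. For knockdown under vehicle it was 728 without dim probe sets, 857 with a trended and robust variance, 90 with the compared arrays only, 41 at a fold of 1.5, 145 at an adjusted p under 0.01 and 169 to 338 without 1 array; under estradiol it was 1117, 1246, 174, 63, 167 and 216 to 547, and 121 with the covariate. The difference of the effects had 2 calls with a trended and robust variance. The averaged estradiol effect had 212 with the covariate, 206 at a fold of 1.5, 1303 at an adjusted p under 0.01 and 2076 to 3725 without 1 array; the averaged knockdown had 863, 43, 535 and 897 to 1274, with 2344 without dim probe sets and 2422 with a trended and robust variance. Fewer calls at stricter thresholds, and fewer with fewer arrays, follow from their construction. The ranges without 1 array also reached above the full-fit counts of 2001, 524 and 2898, which fewer arrays do not explain. Of the array weights, that of vehicle replicate 1 with SRC-1 siRNA was the lowest, at 0.606. The cause of these rises and of the other changes was not tested.

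The induced ratio was 1.352 with median centring, 1.188 with 1 symbol only, 1.057 with the covariate and a set of 168 chosen with it, 1.08 in the set at a fold of 1.5 and 1.203 to 1.485 without 1 array; the repressed ratio was 1.244 without dim probe sets, 1.189 with 1 symbol only, 1.164 at a fold of 1.5 and 1.089 to 1.697 without 1 array. Chosen on the non-targeting effect, the ratios reversed to 0.995 and 0.777. This choice lowers the ratio by its construction, to 0.956 in simulated data with a true ratio of 1. Only increases were simulated, with sizes not matched to these data, so 0.956 does not measure the drop in the repressed set. How much of either drop comes from the choice was not tested. Lists called with an estimated correlation were 1, 1, 0, 0 and 0 over the 5 contrasts. With the covariate 2, 4 and 0 lists were called for estradiol with SRC-1 siRNA, knockdown under estradiol and the difference. Estradiol with SRC-1 siRNA had 3 in the compared arrays, and the difference had 3 with a trended and robust variance and 0 by fry. Without 1 array the lists called were 2 to 5, 2 to 5, 2 to 4, 5 to 8 and 0 to 3; the cause was not tested.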

Other observations

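All splits of the arrays in this part were planned before the data were examined; the covariate and the mean without NCOA1 were chosen after they were seen.

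With the settings chosen beforehand, camera called none of the lists of this paragraph and the next in any of the 5 contrasts, except leukocyte markers for knockdown under estradiol (0.0431, lower), while single members changed. With the covariate it called luminal markers higher with estradiol, at an adjusted p of 0.0123 with non-targeting and 0.00754 with SRC-1 siRNA, and leukocyte markers higher with non-targeting siRNA (0.0239). Fry called luminal markers for estradiol with non-targeting siRNA, osteoblast, growth factor and p53 target genes for estradiol with SRC-1 siRNA, coregulators for knockdown under vehicle, a list that holds the siRNA target NCOA1 and has a mean of -0.007 log2 over its other 25 members, and osteoblast and growth factor genes for knockdown under estradiol. Camera called osteoblast genes without dim probe sets for estradiol with SRC-1 siRNA, and Notch and Hippo targets with a trended and robust variance for knockdown under vehicle. For knockdown under estradiol it called histone genes higher in 8 alternatives, 4 of them without 1 array (estradiol replicate 1 with non-targeting siRNA, 0.0276, and vehicle replicate 3 and estradiol replicates 2 and 3 with SRC-1 siRNA, 0.0353, 0.0321 and 0.0359). Without vehicle replicate 3 with SRC-1 siRNA it called histone genes higher (0.00185) and Notch and Hippo targets lower (0.0238) for knockdown under vehicle. It called the latter lower under estradiol without estradiol replicate 3 with non-targeting siRNA (0.0228), and TGF-beta genes lower for estradiol with non-targeting siRNA without its vehicle replicate 3 (0.0434). Of 22 TGF-beta and BMP response genes, estradiol with non-targeting siRNA raised 1 and lowered 5 (2 and 7 adjusted over the list alone): FST rose 3.06-fold, and ID1, an inhibitor of differentiation, and SMAD6, an inhibitory SMAD, fell by 0.40 and 0.29 log2. SRC-1 siRNA under vehicle raised 3 and lowered 4 (3 and 5 adjusted over the list alone), with TGFBI, a matrix protein, 1.48-fold and INHBA, an activin subunit, 1.47-fold lower. Of 27 growth factors and receptors, estradiol raised 3 and lowered 5 (3 and 7 adjusted over the list alone), with TGFA, a ligand of the EGF receptor, 1.91-fold higher. Of 22 osteoblast genes, estradiol lowered 2 (2 adjusted over the list alone), among them TNFRSF11B, the decoy receptor osteoprotegerin, 1.34-fold, and SRC-1 siRNA under vehicle lowered 3 (3 adjusted over the list alone), among them SPP1, osteopontin, 1.64-fold. Of 20 p53 targets, estradiol raised 2 and lowered 1 (2 and 1 adjusted over the list alone), with PLK2, a polo-like kinase, 2.32-fold higher. Of 28 nuclear receptors, it raised 3 and lowered 1 (3 and 2 adjusted over the list alone), with NR1D1, a clock repressor, 1.74-fold higher, and of 26 coregulators it raised NRIP1, a corepressor, 1.34-fold (1 adjusted over the list alone), a call lost with the covariate.

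Of 15 Notch and Hippo targets, estradiol with non-targeting siRNA raised 1 and lowered 2 (2 and 3 adjusted over the list alone), with JAG1, a Notch ligand, 1.46-fold lower. Among 33 interferon-stimulated genes ISG20, an exonuclease, rose 1.95-fold, the 1 called (1 adjusted over the list alone), and among 23 apoptosis genes 2 fell (2 lower and 1 higher adjusted over the list alone), with BIRC2, an inhibitor of apoptosis, at -0.24 log2, a call lost with the covariate. The 28 ribosome biogenesis and MYC targets had 1 higher and 1 lower (1 and 1 adjusted over the list alone), the latter being MYC, and of 16 heat-shock genes DNAJB4 was lower, at -0.33 log2, a call kept in 8 of the 12 fits that left out 1 array and lost with the covariate. Of 18 luminal epithelial markers 2 rose (4 higher and 1 lower adjusted over the list alone), KRT19 and the mucin gene MUC1, the latter 1.78-fold, and of 11 endothelial markers the transcription factor gene ERG rose 1.48-fold (1 adjusted over the list alone). For estradiol with non-targeting siRNA, limma called 0 members of 6 further lists: 25 GSK3 and Wnt pathway components (5 at an unadjusted p under 0.05, 0 with a trended and robust variance), 18 unfolded protein response genes (1 and 0), 26 ribosomal protein genes (0 and 0), 32 replication-dependent histone genes (1 and 0), 13 siRNA machinery genes (2 and 2) and 15 fibroblast and smooth muscle markers (3 and 1). Members of these lists called by limma in the other comparisons were FZD1, LRP6, HERPUD1, AGO3 and COL1A2 for estradiol with SRC-1 siRNA, DICER1, TAGLN and THY1 for knockdown under vehicle, and CNN1 and TAGLN under estradiol. AGO3, and TAGLN under vehicle, kept their calls in all 12 fits that left out 1 array, FZD1 and CNN1 in 8, LRP6 in 7, HERPUD1 in 4, TAGLN under estradiol in 3, COL1A2 and DICER1 in 2 and THY1 in 1. With the covariate, TAGLN under vehicle kept its call and the others lost theirs.

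Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. The real and highest other counts were 793 and 0 for estradiol with non-targeting siRNA, 2001 and 0 with SRC-1 siRNA, 352 and 1 for knockdown under vehicle and 524 and 0 under estradiol, with 1 split as large in each case. For lists called they were 4 and 4, 5 and 2, 2 and 4, and 7 and 7, with 2, 1, 3 and 2 splits as large. Except for estradiol with SRC-1 siRNA, another split thus called as many lists as the real one or more. Chance is not excluded for the number of lists called in any of these comparisons. Of 100 splits, 1 was as large for the averaged knockdown (1483, highest other 1) and for the averaged estradiol effect (2898, highest other 68). In both cases it is the real grouping itself, so chance is made unlikely for these effects but is not excluded. For the difference of the estradiol effects, limma called 0 probe sets (2102 at an unadjusted p under 0.05, highest other 1), a count that all 100 splits match by construction, which decides nothing. In lists 63 were as large (1 called, highest other 6), so chance is not excluded there.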
